A study of Cyprinodon variegatus with 30 samples.

How the data were processed

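The study measured messenger RNA in whole larvae of the sheepshead minnow, *Cyprinodon variegatus*, an estuarine fish. Per the labels, each library was made from a pool of 5 whole larvae, with total RNA taken by a Qiagen RNeasy kit, a NuGEN mRNA library kit and paired sequencing on an Illumina NovaSeq. The 30 libraries form 10 groups of 3. Of these, 5 groups were sampled at the end of 48 h of exposure, at an age of 6 days after hatching, and 5 after a further 48 h in clean, oxygenated water, at an age of 8 days. The treatments were oil, hypoxia and both together. The labels give 2 separate control groups at each time: 1 called control, with the same stated salinity as the oil groups (15.8 ± 0.5 ppt), and 1 called normoxic control, named for its oxygen (17.0 ± 2.0 ppt, against 15.5 ± 1.0 for hypoxia and 15.3 ± 1.0 for oil plus hypoxia). From these names and values, oil was compared with control, and hypoxia and oil plus hypoxia with normoxic control.

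Every file holds 1 library, and no replicates were pooled. Raw read counts per gene were deposited by the authors as unique and total gene, exon and intron reads, per the file headers. The deposited RPKM values are exon reads per kilobase of exon, scaled to a library total that is larger than the sum of gene reads, and they served here only to read off that total. The TPM values deposited by the authors are scaled to the same total in every library and were not tested. The read mapper, its filters, the strand setting and whether reads or read pairs were counted are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical gene copies can therefore not be told apart, and such genes stay uncertain.

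The files list 25075 genes on 2839 scaffolds, with 24678 distinct gene identifiers. Of these genes, 14530 carry only a locus name (LOC and a number) and 10545 another symbol. Against the NCBI RefSeq table of assembly C_variegatus-1.0, 24633 entries had the same symbol and 24678 the same start and end. Coordinates are those of the files, counted from 1. The gene models differ between the times: 1811 genes, among them the 964 long noncoding RNA genes and the mitochondrial genes, have an exon length of 0 in the 48 h files and none has in the 96 h files, so their reads stand in the intron columns at 48 h. Total gene reads, which do not depend on that difference, were therefore the measure tested.

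Gene reads per library ranged from 19570337 to 34339852, and the share of them mapped uniquely from 95.75% to 98.49%. A count of 3 reads, the upper limit that a count of 0 allows, corresponds to 0.0874 to 0.153 CPM (counts scaled to a common library total) over the libraries. Such floors cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules. No pair of replicates fell within sampling noise: the chi-square per gene lay between 10.92 and 175.1.

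Counts were scaled by the trimmed mean of M values (TMM), and genes were kept by the filterByExpr function with a minimum count of 10 and a minimum total of 15, which left 22441 genes, 12522 of them with a locus name. A quasi-likelihood negative binomial model of edgeR 4.0.16 in R 4.3.3 was fitted with robust settings to all 30 libraries, with 1 term per group, so that all groups share an estimate of the spread on 20 residual degrees of freedom. Each comparison was a contrast of group terms. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene is called changed at an adjusted p under 0.05. Log2 fold changes are given with standard errors derived from the F statistic, and group levels as mean CPM with the standard deviation (SD) of 3 libraries. Recovery was tested as the fold change at 96 h minus that at 48 h, and the oil by oxygen interaction as the effect of oil under hypoxia minus that in oxygenated water. The 2 control groups were compared at each time as a background, and the controls at 96 h with those at 48 h for age. The labels describe separate cups within a treatment but do not tie each library to a cup, so p-values measure the spread between pools of larvae.

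Before the data were examined, the groups, tests, alternatives, gene lists and a rule for naming genes were fixed. The rule takes, in each of the 8 treatment comparisons, the 5 largest rises and the 5 largest falls among called genes with a symbol, a mean log2 CPM of 2 or more and no overlap between the 3 libraries of each group, a lack of overlap that chance alone gives to 10% of genes. It adds up to 4 called members of each list, smallest adjusted p first, and the benchmark genes *ahrr*, *tiparp*, *egln3*, *vegfa*, *bnip3* and *ndrg1* whatever their result. For recovery and interaction it takes the largest changes without the condition on overlap, and the benchmarks. The benchmarks *cyp1a*, *cyp1b1*, *cyp1c1*, *pfkfb4*, *igfbp1*, *ldha*, *hba* and *hbb* were not matched by symbol and were not analysed here. Some genes that the rule takes are not reported here. Locus-named genes fall outside the rule, and the few that appear were chosen after their values were seen.

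The 25 lists covered targets of the aryl hydrocarbon receptor, antioxidant and conjugation genes, targets of hypoxia-inducible factor (HIF), glycolysis, the mitochondrial respiratory chain, red blood cells, digestive enzymes, liver plasma proteins, skeletal muscle, heart, photoreceptors, lens, neurons, collagen and matrix, the cell cycle, cholesterol synthesis, fatty acid oxidation, innate immunity, chaperones, the DNA damage response, the circadian clock, glucocorticoid stress, DNA methylation enzymes, ion transport and cytosolic ribosomal proteins. Members were matched by symbol; *rhob*, *cdc20b* and *acadsb* matched by spelling alone and were left out. Lists with at least 5 tested members, 22 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Of 176 such tests 76 were called, and 2 of these hold with an estimated correlation: skeletal muscle under hypoxia at 48 h and HIF targets under oil plus hypoxia at 48 h. Counts of changed members are given over all genes and adjusted over the list alone.

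The code was tested on simulated counts for oil against control at 48 h (22348 genes, 200 changed, 50 per fold). The edgeR fit recovered 42 of 50 genes raised by a log2 fold of 1, 38 of 50 lowered by as much, 49 of 50 raised by 2 and 50 of 50 lowered by 2, with 10 unchanged genes called. For recovery from oil it recovered 20 of 50 genes moved up by 1 and 23 of 50 moved down by 1. Alternatives covered DESeq2 1.42.0, relative log expression (RLE) scaling, no filter, unique reads, the contrast's libraries alone, a replicate block, the other control group, each library left out, and, added after seeing the data, exon reads, genes with the same model at both times, recovery against the other control set, age within each control set, and removal of each library's trend of expression on exon length by loess. On simulated counts with a planted length trend (22357 genes), that removal took the unchanged genes called from 192 to 7.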

Results

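The series followed gene expression in whole larvae of the sheepshead minnow, *Cyprinodon variegatus*, through exposure to oil, to low oxygen or to both, and through recovery in clean water. Oil is given in the labels as the sum of 50 polycyclic aromatic hydrocarbons (PAHs), 102.5 µg/l in the oil groups and 93.19 µg/l with hypoxia. It was 0.3 µg/l in the other groups. Hypoxia meant dissolved oxygen of at most 2 mg/l in the protocol, and the other groups were held at 5 or above, in a unit the sample labels write as mg/ml. Each of the 10 groups held 3 libraries of 5 pooled larvae, with 19570337 to 34339852 gene reads per library. Fold changes below are log2 values ± standard error (SE) from edgeR's quasi-likelihood test. Adjusted p-values are by Benjamini-Hochberg over 22441 genes, and levels are mean CPM ± SD of 3 libraries.

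Sampling time, and with it age, set the libraries apart more than any treatment. The first principal component, with 38.4% of the variance, separated the 48 h libraries (6 days after hatching) from the 96 h libraries (8 days), and the second held 26% of the variance. In the controls 13711 genes differed between the ages, 7592 of them higher in the older larvae. The muscle chaperone *unc45b* rose by 2.57 ± 0.37 and *hpx*, which encodes the haem scavenger hemopexin of blood plasma, by 2.21 ± 0.27. Of the lists, 17 of 18 cell cycle genes and 12 of 15 collagen and matrix genes rose with age over both control sets. The cell cycle genes did so in control (18 of 18, median 2.59) and not in normoxic control (0 of 18, median −0.17), while 13 and 10 of 15 matrix genes rose in the 2 sets. Of 17 cholesterol genes 14 rose in control and 16 fell in normoxic control. The aryl hydrocarbon receptor repressor gene *ahrr* fell with age by 1.29 ± 0.17.

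**Figure D1:**
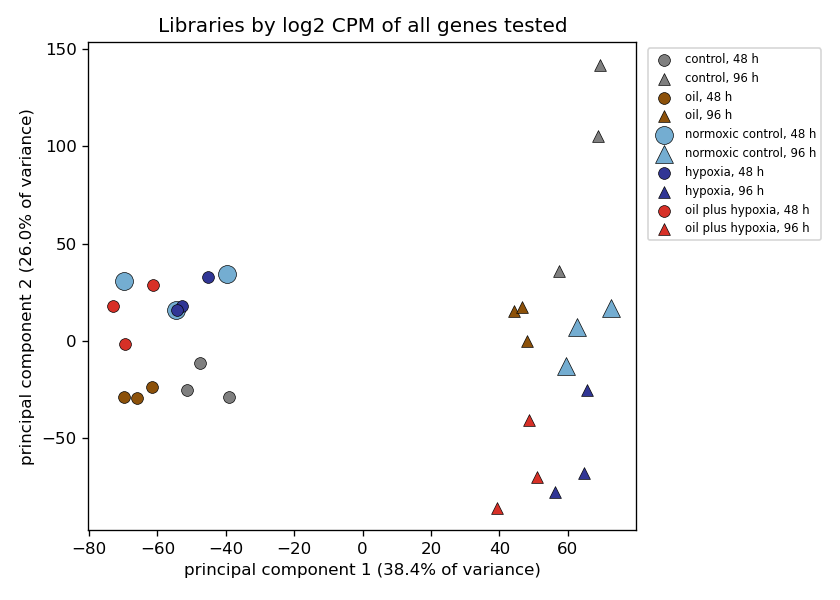
First and second principal components of log2 CPM over all genes tested, with their shares of the variance on the axes, where circles are 48 h and triangles 96 h libraries, colours are treatments, and normoxic controls have larger symbols so that overlapping points show. The 48 h libraries lie to the left and the 96 h libraries to the right.

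The 2 control groups differed from each other before any treatment effect was considered. At 48 h 3695 genes differed between normoxic control and control (1717 higher, 1978 lower), and at 96 h 7465 (2793 higher, 4672 lower). The enzymes of cholesterol synthesis turned between the times. The *sqle* gene, for squalene epoxidase, was higher in normoxic control by 2.91 ± 0.63 at 48 h and lower by 3.72 ± 0.64 at 96 h, where 17 of 17 list members were lower. Cell cycle genes did likewise, with 16 of 18 higher at 48 h and 18 of 18 lower at 96 h. Median SDs of log2 CPM per group were 0.126 to 0.214, apart from 0.299 in control at 96 h. There replicates 1 and 3 had 10.6% and 14.6% of genes over 2-fold from the other 2 libraries. Each effect below was measured against its own control group.

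The first question was what 48 h in oil did. Among the largest rises were *mmp9* and *ahrr*, a gene of the aryl hydrocarbon receptor, which binds PAHs, and among the largest falls *serpinh1* and *sox9*. The matrix metalloproteinase gene *mmp9* rose by 2.34 ± 0.27 (adjusted p = 1.21e-05), from 13.6 ± 1.53 to 69 ± 31.8 CPM. The *ahrr* gene, a direct target of the receptor that also represses it, rose by 1.95 ± 0.23 (adjusted p = 2.27e-05), from 10.3 ± 0.793 to 40 ± 12.5 CPM. Another target, *tiparp*, rose by 0.55 ± 0.13 (adjusted p = 0.0166). The epithelial transcription factor gene *ehf* (1.96 ± 0.38), *unc93a* (1.87 ± 0.38) and the angiopoietin-like gene *angptl5* (1.85 ± 0.26) were the other large rises. The largest falls were *gnmt*, a glycine methyltransferase of liver that uses S-adenosylmethionine (−1.58 ± 0.34), and *serpinh1*, the collagen chaperone (−1.34 ± 0.18, from 46.8 ± 4.67 to 18.5 ± 2.61 CPM). The regulator of cartilage formation *sox9* (−1.14 ± 0.16, from 33.3 ± 0.333 to 15.1 ± 2.51 CPM) also fell, as did *col28a1* (−1.13 ± 0.24) and *angptl4*, which regulates lipoprotein lipase (−1.07 ± 0.22).

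Among the lists at 48 h in oil, 2 of 3 targets of the aryl hydrocarbon receptor rose (3 adjusted over the list alone). Of 13 innate immune genes 3 rose (4 adjusted over the list alone): *mmp9*, the cytokine signalling suppressor *socs3* (1.07 ± 0.17) and *nfkbia*, the inhibitor of NF-kappaB (0.89 ± 0.18). Camera gave the innate list adjusted p = 0.00047, and adjusted p = 0.22 with an estimated correlation. Of 15 antioxidant and conjugation genes 2 rose (3 adjusted over the list alone), glutathione reductase *gsr* (0.76 ± 0.16) and the autophagy receptor *sqstm1* (0.95 ± 0.26). Camera gave this list adjusted p = 0.00047, and adjusted p = 0.25 with an estimated correlation. Cholesterol synthesis had a median of 0.79, with *ebp* (1.56 ± 0.41) and the sterol-sensing regulator *srebf2* (0.55 ± 0.14) the 2 of 17 genes that rose (10 adjusted over the list alone). Its camera result was adjusted p = 6.7e-07, and adjusted p = 0.36 with an estimated correlation. Of 7 glucocorticoid stress genes 2 rose (3 adjusted over the list alone), the liver enzyme gene *tat* (1.51 ± 0.34) and the kinase gene *sgk1* (0.94 ± 0.22). For the stress list camera gave adjusted p = 0.0019, and adjusted p = 0.11 with an estimated correlation. The clock gene *nr1d2* (0.54 ± 0.11) was the 1 of 9 circadian genes that rose (3 adjusted over the list alone). Clock genes had adjusted p = 0.0011, and adjusted p = 0.11 with an estimated correlation.

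Of 15 collagen and matrix genes 1 fell at 48 h in oil, the periostin gene *postn* (−0.90 ± 0.18), and 3 fell when adjusted over the list alone. The list's median was −0.43, with adjusted p = 0.00023, and adjusted p = 0.50 with an estimated correlation. Ribosomal proteins had a median of −0.32 with 0 of 63 called by edgeR (adjusted p = 1.3e-10 by camera, and adjusted p = 0.64 with an estimated correlation). Other lists with no called member had a median of −0.25 in 11 glycolysis genes, −0.16 in 41 respiratory chain genes and −0.36 in 14 photoreceptor genes (2, 0 and 4 lower adjusted over the list alone). Their camera adjusted p of 0.002, 0.0075 and 0.011 became adjusted p = 0.50, adjusted p = 0.83 and adjusted p = 0.64 with an estimated correlation. Of 18 HIF targets, *higd1a*, a small mitochondrial protein gene, rose (1.22 ± 0.22) and *angptl4* fell. The hypoxia benchmarks gave 0.10 ± 0.23 for *egln3*, 0.26 ± 0.12 for *vegfa*, 0.11 ± 0.27 for *bnip3* and −0.26 ± 0.13 for *ndrg1*, none of them called. In the other lists the heat-shock gene *dnajb1* fell (−0.81 ± 0.18) with *serpinh1* among 18 chaperones. The kidney transporter *slc12a1* rose (1.05 ± 0.27) among 10 ion transport genes, and *gnmt* fell among 9 genes of DNA methylation.

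In all 593 genes changed at 48 h in oil, 392 higher and 201 lower. Of the 28 named genes called here, including 4 with a locus name described further on, 15 kept their call whichever of the 6 libraries was left out, *mmp9*, *ahrr*, *socs3*, *higd1a*, *serpinh1* and *sox9* among them. Calls lost were 11, 8 and 7 without control replicate 1, 2 and 3, and 8, 7 and 6 without oil replicate 1, 2 and 3, *tiparp*, *gnmt*, *gsr*, *tat*, *sgk1*, *postn* and *ebp* among them. The call of *sqstm1* was lost without any 1 of the 6 libraries (adjusted p 0.0916 to 0.181), and those of *srebf2*, *dnajb1* and *slc12a1* without 5 of them. With those libraries left out in turn the count was 243, 258, 268, 219, 274 and 343. It was 982 by DESeq2, 1912 in a fit of these 6 libraries alone and 4202 against the normoxic controls, where *ehf*, *gnmt*, *ebp* and *srebf2* differed in the other direction (−0.35, 0.46, −0.86 and −0.18), as did cholesterol synthesis (median −0.92, 5 of 17 lower) and photoreceptor genes (median 0.38, 4 of 14 higher).

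**Figure D2:**
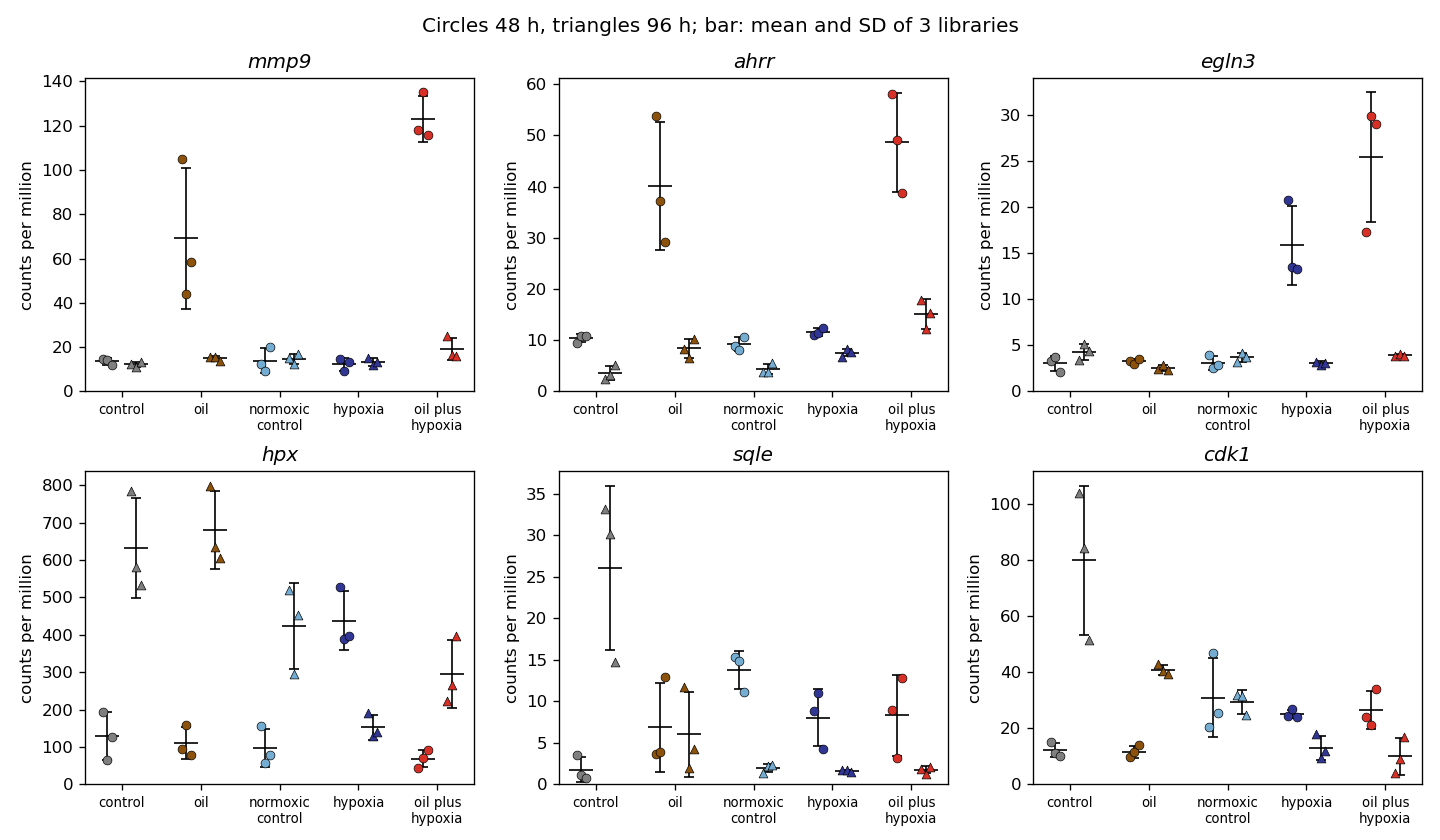
CPM of *mmp9*, *ahrr*, *egln3*, *hpx*, *sqle* and *cdk1* in each library by treatment, with circles for 48 h and triangles for 96 h, and bars for the mean and SD of 3 libraries. At 48 h *mmp9* averaged 13.6 CPM in control and 69 in oil.

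Larvae that had been in oil were compared with control again after 48 h in clean water. Of the lists, 62 of 63 cytosolic ribosomal proteins, 38 of 41 genes of the mitochondrial respiratory chain and 15 of 17 cholesterol genes were lower, and 8 of 14 neuron genes higher. The ribosomal protein gene *rps13* fell by 1.26 ± 0.21 (adjusted p = 0.000625), from 761 ± 313 to 319 ± 73.9 CPM, and *ndufb6*, a subunit of respiratory complex I, by 1.33 ± 0.22 (adjusted p = 0.000625), from 49.8 ± 19 to 19.7 ± 3.46 CPM. Here *ahrr* rose (1.19 ± 0.25, adjusted p = 0.00129, from 3.6 ± 1.43 to 8.39 ± 1.88 CPM). It was 6.8 to 8.26 CPM after hypoxia. After oil *tiparp* was not called (0.09 ± 0.13). The largest rises were *rbm47*, an RNA-binding protein gene (1.98 ± 0.42), *hic2* (1.94 ± 0.50), *rapgefl1* (1.76 ± 0.41), the glycine transporter gene *slc6a5* (1.71 ± 0.53) and *jmy* (1.61 ± 0.43). Among the largest falls were *sqle* (−2.10 ± 0.58, from 26.1 ± 9.89 to 6.03 ± 5.15 CPM), *ebp* (−1.96 ± 0.40) and *fdps* (−1.88 ± 0.49), all of cholesterol synthesis, and the splicing factor gene *ppil1* (−1.49 ± 0.32).

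Group by group at 96 h after oil, 62 of 63 ribosomal proteins fell (63 adjusted over the list alone; median −1.04; adjusted p = 4.9e-24). So did 38 of 41 respiratory chain genes (38 adjusted over the list alone; median −0.98; adjusted p = 2.2e-17) and 15 of 17 cholesterol genes (16 adjusted over the list alone; median −1.32; adjusted p = 2.6e-06). Each of the 3 lists had adjusted p = 0.55 with an estimated correlation. Of 18 chaperones 12 fell (13 adjusted over the list alone), such as the mitochondrial chaperonin *hspd1* (−0.93 ± 0.20). Of 18 cell cycle genes 8 fell (8 adjusted over the list alone), such as the replication clamp gene *pcna* (−1.04 ± 0.31) and the helicase gene *mcm7* (−0.66 ± 0.18). Both lists had adjusted p = 0.0037, against adjusted p = 0.55 and adjusted p = 0.60 with an estimated correlation. Glycolysis had 5 of 11 members lower (8 adjusted over the list alone), *pgk1* (−0.88 ± 0.18) and *gapdh* (−0.94 ± 0.22) among them. Camera gave glycolysis adjusted p = 0.0037, and adjusted p = 0.55 with an estimated correlation. Of 15 antioxidant genes 7 fell and 1 rose (7 and 1 adjusted over the list alone), the superoxide dismutases *sod1* (−1.05 ± 0.18) and *sod2* (−0.82 ± 0.15) among the falls. This list had adjusted p = 0.019, and adjusted p = 0.55 with an estimated correlation. Of 14 neuron genes 8 rose (8 adjusted over the list alone), including the synaptic vesicle gene *syn2* (0.71 ± 0.18) and the neuronal RNA-binding gene *elavl4* (1.26 ± 0.39). Neuron genes had adjusted p = 0.0037, and adjusted p = 0.56 with an estimated correlation.

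Lists that camera did not call at 96 h after oil still held called members. The DNA methyltransferase gene *dnmt3a* (1.66 ± 0.46) and the demethylase gene *tet2* (1.54 ± 0.48) were among 3 of 9 DNA methylation genes that rose. Of 9 clock genes 3 rose, *per1* (0.71 ± 0.19) and *per2* (0.98 ± 0.31) among them, and 1 fell, and the glucocorticoid receptor gene *nr3c1* rose by 1.33 ± 0.42. Skeletal muscle had 3 of 7 members lower, *mylpf* (−1.04 ± 0.20) and *acta1* (−0.88 ± 0.19) among them. Fatty acid oxidation had 9 of 18 lower and 2 higher, and heart 4 of 11 higher and 2 lower, with the atrial peptide gene *nppa* at −1.06 ± 0.25. Of the lens list 3 members fell, of the liver plasma list 3, of DNA damage response genes 3, of the innate immune list 4 (1 rose), of photoreceptor genes 4 (1 rose) and of the red blood cell list 1. Among HIF targets 5 fell and 1 rose, with *egln3* at −0.76 ± 0.23 (adjusted p = 0.015). Adjusted over the list alone the counts were the same, apart from 11 lower for fatty acid oxidation, 3 lower for heart and 0 for the innate immune list. The benchmarks *vegfa*, *bnip3* and *ndrg1* at −0.09 ± 0.12, 0.04 ± 0.29 and −0.22 ± 0.13 were not called.

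In all 8759 genes differed at 96 h after oil, 3819 higher and 4940 lower. Across 14986 genes the fold change rose with exon length (Spearman correlation 0.61, over genes, which are not independent replicates). The 96 h control libraries lay apart most of all groups on that axis. Deviations of replicate 1, 2 and 3 from their mean correlated with exon length at −0.6, −0.44 and 0.64 (Spearman). With the length trend removed 6778 genes were called, and 7 of the 8 lists called by camera kept call and direction. Of 35 named genes 22 kept their call whichever library was left out. Calls lost were 12 and 7 without control replicate 1 and 2, and 4 and 9 without oil replicate 1 and 3, those of *elavl4*, *per2* and *nr3c1* without 4 of the 6 libraries, *slc6a5*, *tet2* and *egln3* without 3, *pcna*, *dnmt3a* and *per1* without 2, and *sqle*, *mcm7* and *syn2* without 1. The count was 2503, 4124 and 4528 without control replicate 1, control replicate 2 and oil replicate 3. Against the normoxic controls it was 4565, and there *sqle*, *ebp*, *fdps*, *nppa*, *mcm7*, *pcna*, *hspd1* and *ppil1* were higher after oil (1.62, 1.1, 0.66, 1.59, 0.70, 0.64, 0.53 and 0.33) and *syn2* was at −0.09. In that comparison 54 of 63 ribosomal proteins and 32 of 41 respiratory chain genes were lower, while 4 of 17 cholesterol and 6 of 18 cell cycle genes were higher (medians 0.56 and 0.83), and chaperones and neuron genes had medians of 0.21 and −0.05. In a fit of these 6 libraries alone edgeR called 0 genes, with 6162 at an unadjusted p under 0.05, and DESeq2 on all libraries called 9319.

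**Figure D3:**
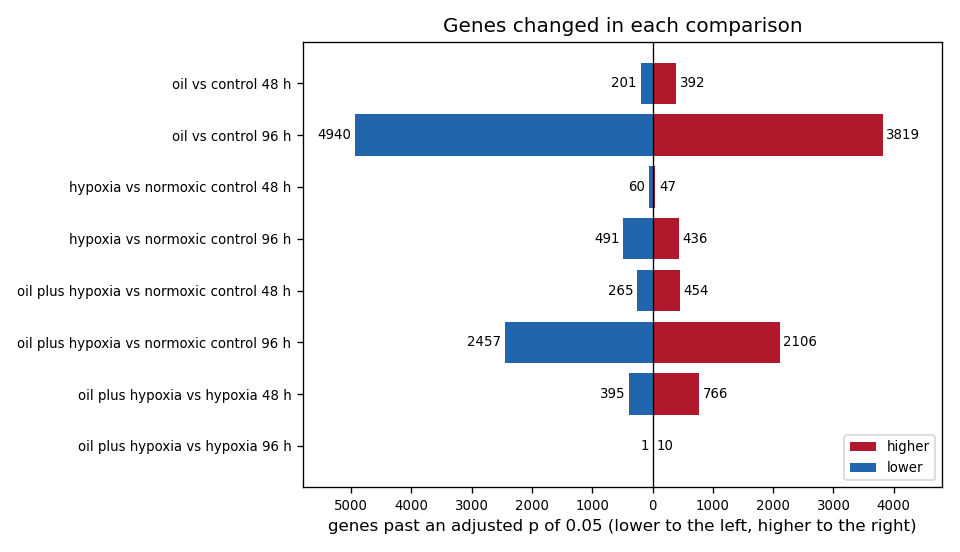
Number of genes called higher (to the right) and lower (to the left) in each of the 8 treatment comparisons at an adjusted p under 0.05. Oil at 96 h has the longest bars, with 3819 higher and 4940 lower, and oil plus hypoxia against hypoxia at 96 h the shortest, with 10 and 1.

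Low oxygen alone for 48 h changed few genes, and the clearest was a known sensor of oxygen. The prolyl hydroxylase gene *egln3*, which marks HIF for breakdown and is itself induced by HIF, rose by 2.35 ± 0.23 (adjusted p = 4.54e-06), from 3.12 ± 0.754 to 15.9 ± 4.26 CPM. Hemopexin, *hpx*, rose by 2.18 ± 0.38 (adjusted p = 0.00498), from 96.8 ± 51.3 to 438 ± 78.2 CPM. The lactate transporter gene *slc16a1* rose by 1.35 ± 0.19 (adjusted p = 0.000389), from 5.68 ± 0.994 to 14.5 ± 1.1 CPM. Falls included some immediate early genes, which cells switch on within minutes of a stimulus. They were *ier2* (−2.58 ± 0.39, from 47.2 ± 32.3 to 7.88 ± 1.22 CPM), *egr1* (−2.5 ± 0.38, from 133 ± 92.4 to 23.6 ± 2.42 CPM), *klf4* (−1.85 ± 0.33) and *atf3* (−1.58 ± 0.28). The normoxic controls varied widely in these genes, with *egr1* at 32.4, 153 and 214 CPM in replicates 1, 2 and 3, while control at 48 h lay at 38.5 to 46.6 CPM.

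**Figure D4:**
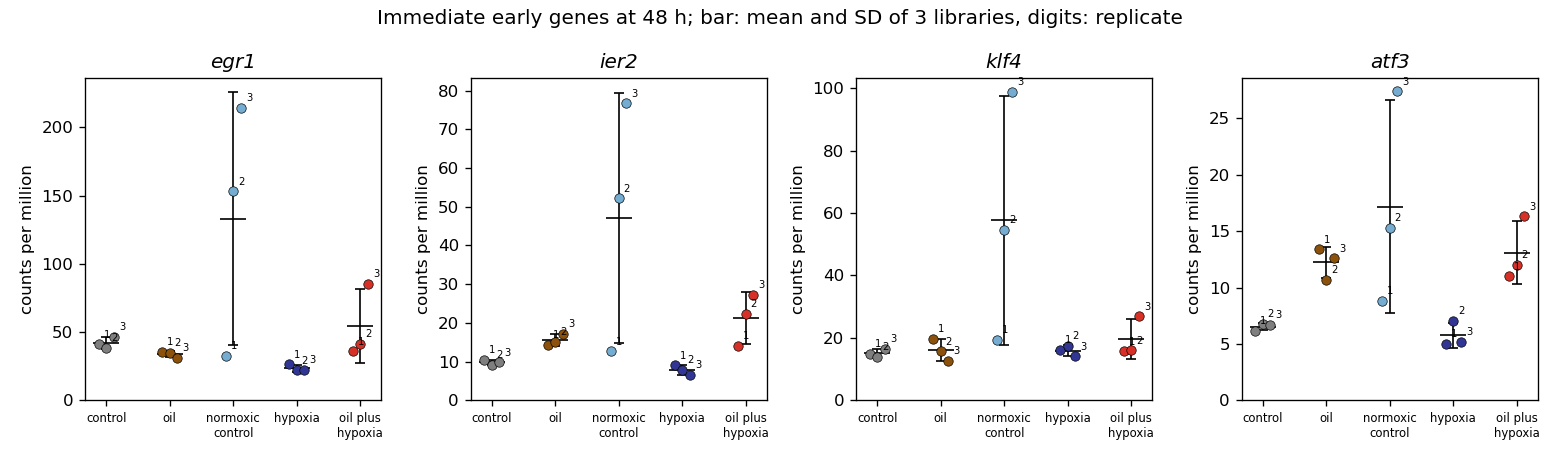
CPM of *egr1*, *ier2*, *klf4* and *atf3* in each 48 h library by treatment, with replicate numbers beside the points and bars for the mean and SD of 3. In *egr1* the normoxic controls spread from 32.4 to 214 CPM, and the hypoxia libraries from 22 to 26.4 CPM.

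Skeletal muscle was the 1 list whose call under hypoxia at 48 h held with an estimated correlation, and that call was lost against the other control set. Its 7 members had a median of 0.59, 1 rose (the sarcomere gene *actn3*, 0.68 ± 0.15) and 5 rose when adjusted over the list alone. Camera gave the muscle list adjusted p = 2.3e-09, and adjusted p = 0.039 with an estimated correlation. Against control, 0 of 7 were called by edgeR, with a median of −0.02 and adjusted p = 0.63 by camera. In normoxic control itself 6 of 7 muscle genes were lower than in control at 48 h (median −0.58). Of 18 HIF targets *egln3* rose and no other, 2 adjusted over the list alone, with adjusted p = 0.016, and adjusted p = 0.23 with an estimated correlation. The liver plasma list had 1 of 9 higher (3 adjusted over the list alone, median 0.35) and the clock list 1 of 9, the clock-output gene *dbp* at 0.84 ± 0.18 (4 up and 1 down adjusted over the list alone, median 0.28). Lens and glycolysis had 0 of 6 and 0 of 11 called by edgeR (1 each adjusted over the list alone, medians 0.53 and 0.26). Camera called liver plasma, lens, glycolysis and clock higher, with adjusted p = 4.4e-05, 0.0004, 0.0012 and 0.014. They had adjusted p = 0.23, adjusted p = 0.33, adjusted p = 0.40 and adjusted p = 0.23 with an estimated correlation. Camera also called ribosomal proteins (median 0.15), the respiratory chain (0.09) and collagen and matrix (0.20) higher and cholesterol synthesis (−0.43) lower, with 0 members called by edgeR in any of them. These had adjusted p = 0.67, adjusted p = 0.68, adjusted p = 0.63 and adjusted p = 0.58 with an estimated correlation. The other called members were *atf3* among chaperones and *gadd45b* (−1.79 ± 0.39) among DNA damage response genes. Innate immune genes had a median of −0.06 and a mean of −0.22 while camera's direction was up (adjusted p = 0.94). The benchmarks *ahrr* (0.32 ± 0.23), *tiparp* (0.02 ± 0.13), *vegfa* (0.04 ± 0.12), *bnip3* (0.47 ± 0.28) and *ndrg1* (−0.12 ± 0.13) were not called.

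At 48 h of hypoxia 47 genes were higher and 60 lower. Of 14 named genes 6 kept their call whichever library was left out, *egln3*, *slc16a1*, *egr1* and *ier2* among them. Without normoxic control replicate 3 the calls of *hpx* (adjusted p 0.000483 to 0.0743 over the libraries left out), *klf4*, *atf3*, *dbp*, *gadd45b*, *actn3*, *fam65c* (0.87 ± 0.15 with all libraries) and the bile acid gene *hsd3b7* (−1.29 ± 0.25) were lost. There were 6, 2 and 6 calls lost without hypoxia replicate 1, 2 and 3. The count was 316 without normoxic control replicate 1, 20 without replicate 3, and 38, 38 and 45 without hypoxia replicate 1, 2 and 3. It was 257 by DESeq2, 166 with the length trend removed, and 16 in a fit of these libraries alone. Against control it was 1250, and there *klf4*, *hsd3b7* and *actn3* were at 0.08, 0.29 and −0.01, the calls of *egr1*, *ier2*, *atf3* and *gadd45b* were lost (−0.84, −0.32, −0.18 and −0.15), 10 of 17 cholesterol genes were higher (median 1.13), and lens and ribosomal protein medians were −0.26 and −0.07.

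Larvae from hypoxia were compared with normoxic control again after 48 h back in oxygenated water. The anion exchanger gene *slc4a1* of red blood cells fell by 1.74 ± 0.46 (adjusted p = 0.0452), from 56.2 ± 1.27 to 16.8 ± 7.29 CPM, and *hpx*, higher at 48 h, was lower by 1.47 ± 0.37 (adjusted p = 0.0433). The glycosyltransferase gene *b3gnt5* (−1.57 ± 0.26), the glycogen breakdown kinase gene *phkg1* (−1.39 ± 0.32) and *klhl40*, which stabilises muscle thin filaments (−1.38 ± 0.36), were the other large falls. The autophagy receptor gene *calcoco1* (2.88 ± 0.83), the lipid kinase gene *pikfyve* (1.68 ± 0.44), the calcium channel gene *cacna2d2* (1.51 ± 0.39) and the synaptic scaffold gene *shank2* (1.33 ± 0.38) were among the largest rises. The benchmarks *egln3* (−0.28 ± 0.23), *ahrr* (0.79 ± 0.24, adjusted p = 0.0571), *bnip3* (0.60 ± 0.28), *tiparp* (0.01 ± 0.13), *vegfa* (−0.10 ± 0.12) and *ndrg1* (−0.01 ± 0.13) were not called.

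Cell cycle genes had the lowest median at 96 h after hypoxia, −0.86, with 1 of 18 called (the spindle checkpoint gene *bub1b*, −1.08 ± 0.30) and 13 lower when adjusted over the list alone. Camera gave cell cycle genes adjusted p = 3.2e-06, which became adjusted p = 0.58 with an estimated correlation. Neuron genes had a median of 0.59, with *syn2* (0.80 ± 0.18) and *cplx1* (0.55 ± 0.14) the 2 of 14 that rose and 9 rising when adjusted over the list alone. Their camera result was adjusted p = 0.0004, and adjusted p = 0.58 with an estimated correlation. The respiratory chain (median −0.35, 0 of 41 called by edgeR, adjusted p = 3.3e-06) and ribosomal proteins (median −0.17, 0 of 63, adjusted p = 0.0073) lay lower, against adjusted p = 0.62 and adjusted p = 0.75 with an estimated correlation. Of 18 fatty acid oxidation genes 2 fell (5 adjusted over the list alone), *hadhb* (−0.54 ± 0.13) and *acads* (−0.62 ± 0.17). Of 15 antioxidant genes 1 fell (3 adjusted over the list alone), *sod1* (−0.65 ± 0.18). Of 18 chaperones 2 fell, *serpinh1* (−0.65 ± 0.18) and *xbp1* (−0.56 ± 0.16), while collagen and matrix genes had a median of −0.37 with none called. These 4 lists were called lower by camera and had adjusted p = 0.58, adjusted p = 0.58, adjusted p = 0.58 and adjusted p = 0.62 with an estimated correlation. With the length trend removed ribosomal proteins lay higher by camera (adjusted p = 0.0017), and the calls of the respiratory chain, fatty acid, antioxidant and chaperone lists were lost. Single members of other lists were *tpi1* of glycolysis (−0.87 ± 0.20), *sc5d* of cholesterol synthesis (−0.95 ± 0.26) and *nr1d2* of the clock (0.53 ± 0.12).

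In all 927 genes differed at 96 h after hypoxia, 436 higher and 491 lower. With RLE scaling the split was 829 higher of 1220. Fold changes followed exon length (Spearman correlation 0.46 across genes), and 569 genes were called with that trend removed. The call of each gene named here was lost on leaving out at least 1 library. EdgeR called 0, 1 and 9 genes without normoxic control replicate 1, 2 and 3, and 3547, 0 and 0 without hypoxia replicate 1, 2 and 3, with 4320, 3887 and 4007 at an unadjusted p under 0.05 where it called 0. DESeq2 on all libraries called 2694 genes, a fit of these libraries alone 2339, and the comparison with control 13195.

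**Figure D5:**
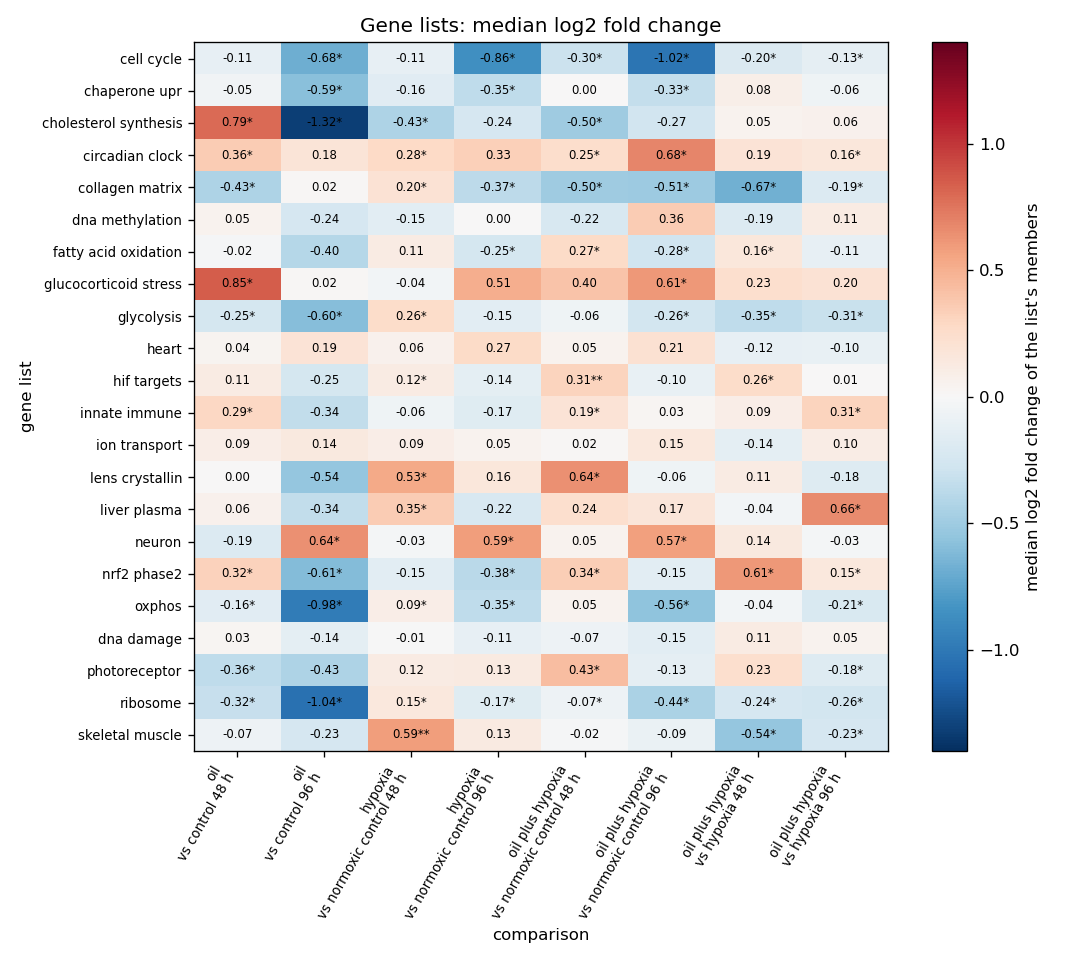
Median log2 fold change of the tested members of each gene list in the 8 treatment comparisons, as a colour scale, where * marks an adjusted p under 0.05 by camera with the preset correlation and ** one that also holds with an estimated correlation. The ** squares are skeletal muscle under hypoxia at 48 h, with a median of 0.59, and HIF targets under oil plus hypoxia at 48 h, with a median of 0.31.

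Oil and hypoxia together for 48 h raised the genes that led the response to oil and the oxygen sensor gene that led the response to hypoxia. Against normoxic control *mmp9* rose by 3.15 ± 0.28 (adjusted p = 4.86e-08). The *egln3* gene rose by 3.03 ± 0.23 (adjusted p = 4.62e-09), from 3.12 ± 0.754 to 25.4 ± 7.02 CPM, and the *ahrr* gene by 2.39 ± 0.24 (adjusted p = 4.2e-07), from 9.26 ± 1.32 to 48.6 ± 9.66 CPM. The growth factor gene *fgf7*, which acts on epithelia, rose by 2.58 ± 0.26, from 4.18 ± 1.03 to 25.1 ± 1.72 CPM, *unc93a* by 2.08 ± 0.38 and *tiparp* by 0.87 ± 0.13. The largest falls were the oxidase organiser gene *noxo1* (−2.13 ± 0.49) and *sox9* (−1.57 ± 0.16, from 40.5 ± 9.69 to 13.6 ± 1.98 CPM). Next came the recombinase gene *rag1* of developing lymphocytes (−1.52 ± 0.38), the signalling gene *wnt2* (−1.49 ± 0.27) and the transglutaminase gene *tgm2* (−1.34 ± 0.32).

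HIF targets rose as a list under the combined exposure, with 5 of 18 higher and 1 lower (7 and 1 adjusted over the list alone; median 0.31). Camera gave them adjusted p = 2e-05, a call that held with an estimated correlation (adjusted p = 0.021), and against control 8 of 18 rose (adjusted p = 0.05 with an estimated correlation). They were led by *egln3*, *higd1a* (1.57 ± 0.22), the oxidative folding gene *ero1a* (1.18 ± 0.19) and *egln1*, another prolyl hydroxylase (0.66 ± 0.14). The benchmarks *vegfa* (0.34 ± 0.12), *bnip3* (0.77 ± 0.28) and *ndrg1* (0.28 ± 0.13) were not called. Of 15 antioxidant genes 3 rose (7 adjusted over the list alone), *gsr* (0.85 ± 0.16), thioredoxin *txn* (0.83 ± 0.20) and the export pump gene *abcc2* (0.94 ± 0.22). These had adjusted p = 0.00013, and adjusted p = 0.17 with an estimated correlation. Of 15 collagen and matrix genes 2 fell (7 adjusted over the list alone), *postn* (−1.08 ± 0.18) and *col1a2* (−1.01 ± 0.26). Matrix genes had adjusted p = 2e-05, and adjusted p = 0.32 with an estimated correlation. Clock genes had 3 of 9 members higher (3 adjusted over the list alone), *dbp* (1.06 ± 0.18) and *nr1d1* (1.07 ± 0.22) among them. Photoreceptor genes had 2 of 14 higher (5 adjusted over the list alone), *rpe65* (1.13 ± 0.17) and *rlbp1* (0.56 ± 0.16) of the visual cycle, and fatty acid oxidation had 1 of 18 (2 adjusted over the list alone). In that order the 3 lists had adjusted p = 0.17, adjusted p = 0.32 and adjusted p = 0.17 with an estimated correlation. Innate immune genes had 3 of 13 members higher, *mmp9* and *socs3* (1.08 ± 0.17) among them (3 up and 1 down adjusted over the list alone; adjusted p = 0.041, and adjusted p = 0.39 with an estimated correlation).

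Further lists called by camera under the combined exposure at 48 h were lens (median 0.64, 0 of 6 called and 5 higher adjusted over the list alone), cholesterol synthesis (median −0.50, 1 of 17 lower, 2 adjusted over the list alone), cell cycle (median −0.30) and ribosomal proteins (median −0.07). These 4 lists had adjusted p = 0.32, adjusted p = 0.32, adjusted p = 0.69 and adjusted p = 0.85 with an estimated correlation. In glycolysis *aldoc* rose (0.43 ± 0.11) and *gpi* fell (−0.84 ± 0.22), and the ammonia channel gene *rhbg* of gill and kidney fell by 0.91 ± 0.17. In all 719 genes changed, 454 higher and 265 lower. Oil plus hypoxia replicate 1 had 10.98% of the reads of its genes with an exon model in introns, against 1.82 to 3.99% in the other 29 libraries. Without it 375 genes were called, and 479 without normoxic control replicate 1. Of 31 named genes 22 kept their call whichever library was left out, *mmp9*, *egln3*, *ahrr*, *fgf7*, *sox9* and *higd1a* among them. Calls lost were 9, 6 and 2 without normoxic control replicate 1, 2 and 3 and 7, 4 and 7 without oil plus hypoxia replicate 1, 2 and 3, *noxo1*, *rag1*, *tgm2*, *col1a2*, *txn* and *abcc2* among them, with *rlbp1* lost without any 1 of the 6 libraries and *aldoc* without 5. The count was 181 in a fit of these libraries alone. Against control it was 3505, and there *noxo1* and *tgm2* were at 0.42 and 0.13, 11 of 17 cholesterol and 8 of 18 cell cycle genes were higher (medians 1.11 and 0.92), and lens and photoreceptor medians were −0.18 and −0.26.

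At 96 h after the combined exposure 28 of 41 respiratory chain genes and 11 of 18 cell cycle genes were lower, and 4 of 9 clock genes and 6 of 14 neuron genes higher. The cyclin-dependent kinase gene *cdk1*, which drives mitosis, fell by 1.55 ± 0.36 (adjusted p = 0.00972), from 29.4 ± 4.13 to 9.99 ± 6.55 CPM, and *tpi1* of glycolysis by 1.33 ± 0.21 (adjusted p = 0.00126), from 742 ± 41.7 to 295 ± 86 CPM. The other large falls were *klhl40* (−1.78 ± 0.36), *b3gnt5* (−1.77 ± 0.26), *tgm2* (−1.59 ± 0.31) and *gpx7*, a peroxidase of the endoplasmic reticulum (−1.56 ± 0.51). The largest rises were *calcoco1* (4.98 ± 0.89, from 4.26 ± 2.03 to 136 ± 181 CPM, so the treated libraries differed widely) and the histidine lyase gene *hal* (2.09 ± 0.40). After them came the lipid transfer gene *pltp* (1.86 ± 0.61), *ahrr* (1.78 ± 0.24, adjusted p = 0.000731, from 4.39 ± 0.96 to 15.1 ± 2.95 CPM) and the fatty acid transporter gene *slc27a6* (1.72 ± 0.41). The *lox* gene, whose enzyme crosslinks collagen, rose by 1.21 ± 0.23 and *bnip3* by 0.93 ± 0.28 (adjusted p = 0.0241). The benchmarks *egln3* (0.08 ± 0.23), *tiparp* (0.22 ± 0.13), *vegfa* (0.03 ± 0.12) and *ndrg1* (−0.06 ± 0.13) were not called.

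In these larvae 28 of 41 respiratory chain genes fell (34 adjusted over the list alone; median −0.56), such as *ndufb6* (−0.93 ± 0.21) and *ndufs7* (−0.65 ± 0.15). So did 11 of 18 cell cycle genes (16 adjusted over the list alone; median −1.02), such as the mitotic genes *tpx2* (−1.11 ± 0.29), *ccna2* (−1.21 ± 0.32) and *ccnb1* (−1.23 ± 0.33). Camera gave them adjusted p = 1.6e-11 and 7.2e-08, and both had adjusted p = 0.50 with an estimated correlation. Of 15 collagen and matrix genes 7 fell (10 adjusted over the list alone), *col10a1* (−1.01 ± 0.25) and *sparc* (−0.89 ± 0.23) among them, and of 11 glycolysis genes 5 (5 adjusted over the list alone). Of 18 fatty acid oxidation genes 6 fell (6 adjusted over the list alone), *hadhb* (−0.80 ± 0.14), *acads* (−0.91 ± 0.17) and *cpt1b* (−1.20 ± 0.26) among them. Matrix, glycolysis and fatty acid lists had adjusted p = 0.50, adjusted p = 0.50 and adjusted p = 0.47 with an estimated correlation. Ribosomal proteins had a median of −0.44 with 4 of 63 lower and none adjusted over the list alone (adjusted p = 4.8e-10, and adjusted p = 0.69 with an estimated correlation). Another 3 of 18 chaperones fell (1 adjusted over the list alone; adjusted p = 0.55 with an estimated correlation). Of 9 clock genes 4 rose (5 adjusted over the list alone), including *per1* (0.99 ± 0.19), *nr1d2* (0.68 ± 0.12) and *dbp* (0.74 ± 0.18). Of 14 neuron genes 6 rose (9 up and 1 down adjusted over the list alone), including *syn2* (0.80 ± 0.18) and *syt1* (1.24 ± 0.37), and of 7 glucocorticoid stress genes 2 rose (2 adjusted over the list alone), *tat* (1.07 ± 0.34) and *sgk1* (0.61 ± 0.22). The clock, neuron and stress lists had adjusted p = 0.47, adjusted p = 0.70 and adjusted p = 0.47 with an estimated correlation. Lists not called by camera held, among others, *sod2* (−0.61 ± 0.15) of the antioxidant genes, the complement gene *c5* (1.14 ± 0.29), *sesn1* (1.36 ± 0.38) of the DNA damage response genes, and 2 of 4 red blood cell genes, which fell.

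In all 4563 genes differed at 96 h after the combined exposure, 2106 higher and 2457 lower, with a Spearman correlation of 0.48 between fold change and exon length across genes. With that trend removed camera's calls of ribosomal proteins, chaperones, clock and neuron genes were lost (adjusted p = 0.39, 0.077, 0.063 and 0.12). Of 38 named genes 12 kept their call whichever library was left out, *ahrr*, *calcoco1*, *lox*, *tpi1*, *hadhb*, *acads*, *klhl40*, *b3gnt5*, *nr1d2* and *per1* among them. Calls lost were 20, 16, 26 and 8 without normoxic control replicate 1 and 2 and oil plus hypoxia replicate 1 and 2, *cdk1*, *bnip3*, *tat*, *sgk1* and *sesn1* among them, and *pltp*, *gpx7*, *tpx2*, *ccna2*, *ccnb1* and *syt1* without 4 of the 6 libraries. The count was 374 and 878 without those controls, and 1.1e+02 and 1359 without those treated libraries. It was 13726 against control, where *cpt1b* was at 0.22.

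Adding oil to hypoxia, with hypoxia itself as the reference, showed what oil did at low oxygen. The *mmp9* gene rose by 3.33 ± 0.28 (adjusted p = 3.54e-08), from 12.2 ± 2.86 CPM. Other large rises were *unc93a*, by 2.35 ± 0.39, *fgf7* by 2.34 ± 0.26 and *ahrr* by 2.07 ± 0.24 (adjusted p = 4.23e-06). Hemopexin, raised by hypoxia alone, was lower with oil by 2.67 ± 0.39 (adjusted p = 0.000138), from 438 ± 78.2 to 68.7 ± 23.3 CPM. The other large falls were *wnt2* (−1.84 ± 0.27), the endothelial gene *plvap* (−1.52 ± 0.28), *proca1* (−1.48 ± 0.22) and *tgm2* (−1.38 ± 0.32). The benchmark *tiparp* rose by 0.85 ± 0.13, and *egln3* (0.68 ± 0.21, adjusted p = 0.0605), *ndrg1* (0.40 ± 0.13, adjusted p = 0.0624), *vegfa* (0.30 ± 0.12) and *bnip3* (0.30 ± 0.28) were not called.

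Of 15 antioxidant genes 7 rose on adding oil to hypoxia at 48 h (8 adjusted over the list alone; median 0.61), led by *gsr* (1.1 ± 0.16), *gclm* of glutathione synthesis (1.09 ± 0.19), *txn* (0.98 ± 0.20) and *abcc2* (1.06 ± 0.23). Camera gave antioxidant genes adjusted p = 3.3e-06, and adjusted p = 0.14 with an estimated correlation. Collagen and matrix genes had 5 of 15 lower (12 lower and 1 higher adjusted over the list alone; median −0.67), *postn* (−1.23 ± 0.18), *col1a2* (−1.22 ± 0.26), *col6a2* (−0.71 ± 0.17) and *col11a1* (−0.89 ± 0.22) among them. They had adjusted p = 1.8e-08, and adjusted p = 0.24 with an estimated correlation. Of 7 skeletal muscle genes 3 fell (5 adjusted over the list alone), *cacna1s* (−0.69 ± 0.17), *acta1* (−0.68 ± 0.19) and *actn3* (−0.56 ± 0.15). For muscle camera gave adjusted p = 2.3e-06, and adjusted p = 0.14 with an estimated correlation. Of 18 HIF targets 4 rose and 1 fell (7 and 1 adjusted over the list alone). Here *higd1a* (1.58 ± 0.22), *ero1a* (0.93 ± 0.19) and the stress gene *ddit4* (1.83 ± 0.45) rose and *lox* fell (−1.26 ± 0.23, from 26.9 ± 4.81 to 11.1 ± 4.7 CPM). HIF targets had adjusted p = 0.024, and adjusted p = 0.24 with an estimated correlation. Fatty acid genes had 2 of 18 higher (3 adjusted over the list alone), the lipid droplet gene *plin2* (1.06 ± 0.20) among them, and glycolysis 1 of 11 lower (3 adjusted over the list alone), *gpi* (−1.1 ± 0.22). Ribosomal proteins and the cell cycle had medians of −0.24 and −0.20 with none called. The lists of fatty acids, glycolysis, ribosome and cell cycle had adjusted p = 0.60, adjusted p = 0.54, adjusted p = 0.63 and adjusted p = 0.68 with an estimated correlation. Innate immune genes had 4 of 13 higher, *socs3* (1.30 ± 0.17) and *nfkbia* (0.72 ± 0.18) among them, without a call by camera (adjusted p = 0.12). In ion transport *rhbg* fell by 1.08 ± 0.17, and the 3 digestive enzyme genes, too few to test, had a median of −1.15 with none called.

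In all 1161 genes changed on adding oil to hypoxia at 48 h, 766 higher and 395 lower. With the length trend removed 717 were higher and 645 lower. Of 34 named genes 25 kept their call whichever library was left out. Calls lost were 3, 2 and 7 without hypoxia replicate 1, 2 and 3 and 6, 3 and 4 without oil plus hypoxia replicate 1, 2 and 3, *abcc2*, *ero1a*, *ddit4*, *nfkbia*, *col6a2*, *col11a1*, *acta1*, *actn3* and *cacna1s* among them. The count was 524, 620 and 511 without hypoxia replicate 1, 2 and 3, and 497 and 702 without oil plus hypoxia replicate 1, the library rich in intron reads, and replicate 3.

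At 96 h 11 genes differed between oil plus hypoxia and hypoxia, 10 higher and 1 lower, of which 4 and 1 were called in the same direction at 48 h, and *lox* was the one with a symbol. It was higher by 1.28 ± 0.23 (adjusted p = 0.0197), from 11.2 ± 0.545 to 27.2 ± 2.78 CPM, against a fall at 48 h, a difference not tested between the times for this pair of groups. The call was lost without hypoxia replicate 1, 2 or 3 or oil plus hypoxia replicate 1 or 2 (adjusted p 0.026 to 0.226 over the libraries left out). The 1 lower gene, chosen after its values were seen, was LOC107096735 (−1.15 ± 0.22, adjusted p = 0.0385), lost without replicate 1 or 2 of either group (adjusted p 0.0127 to 0.445). The benchmark *ahrr* was at 0.99 ± 0.23 (adjusted p = 0.224) and *egln3*, *tiparp*, *vegfa*, *bnip3* and *ndrg1* were at 0.36 ± 0.23, 0.22 ± 0.13, 0.13 ± 0.12, 0.33 ± 0.27 and −0.05 ± 0.13. Camera called 11 lists, among them ribosomal proteins (median −0.26, adjusted p = 1.1e-13) and the respiratory chain (−0.21, adjusted p = 1.8e-08). The others were glycolysis (−0.31), skeletal muscle (−0.23), collagen and matrix (−0.19), photoreceptors (−0.18), liver plasma proteins (0.66), innate immune genes (0.31), the clock (0.16) and antioxidant genes (0.15), and cell cycle genes. None held with an estimated correlation (adjusted p = 0.44 with an estimated correlation for ribosomal proteins and the respiratory chain). Cell cycle genes had a median of −0.13 and a mean of 0.11, and camera's direction was down (adjusted p = 0.0099, and adjusted p = 0.57 with an estimated correlation). The count was 7 without replicate 1 or 2 of either group, 29 by DESeq2, and 1102 genes passed an unadjusted p under 0.05.

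Large responses to oil were also seen in genes that carry only a locus name, chosen here after their values were seen. LOC107088618 (scaffold NW_015150464.1, 820258 to 827666, minus strand, protein coding) averaged 23.8 CPM in control and 441 in oil at 48 h (4.21 ± 0.28), 19.9 in normoxic control, 63.6 in hypoxia (1.68 ± 0.25) and 952 in oil plus hypoxia (5.58 ± 0.30, adjusted p = 4.75e-12). It was still higher at 96 h after oil (2.08 ± 0.26), after oil plus hypoxia (3.01 ± 0.27) and against hypoxia (2.12 ± 0.26, adjusted p = 7.05e-05), calls kept with each library left out. LOC107089910 (scaffold NW_015150724.1, 926146 to 929593, minus strand) rose at 48 h by 3.63 ± 0.32 in oil, 2.08 ± 0.30 in hypoxia and 5.25 ± 0.35 in both, and at 96 h by 3.14 ± 0.32 after both. The largest falls in oil were LOC107105043 and LOC107100620, by 4.92 and 3.37 at 48 h, and against hypoxia by 4.37 and 4.09. Neither the files nor the reference table pair these loci with a product name.

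Whether the responses faded in clean water was tested as a difference between the times. The effect of hypoxia on *egln3* shrank by 2.63 ± 0.33 (adjusted p = 0.00022), and that of oil plus hypoxia by 2.95 ± 0.32 (adjusted p = 1.05e-05). In the combined exposure *mmp9* (−2.76 ± 0.37), *higd1a* (−2.45 ± 0.31), the BMP antagonist gene *grem1* (−1.84 ± 0.32) and *rpe65* (−1.68 ± 0.25) also came down. Of the others *lox* (2.22 ± 0.32), *wnt2* (1.63 ± 0.38), *lepr* (1.41 ± 0.34), *papln* (1.26 ± 0.27) and *sox9* (1.11 ± 0.22) moved up. In all 223 genes moved (45 up, 178 down), against 215 up and 141 down in a fit of these libraries alone. After hypoxia 37 genes moved (7 up, 30 down). They included *hpx* (−3.65 ± 0.53), *slc4a1* (−3.04 ± 0.64) and *slc16a1* (−1.60 ± 0.27) among those down, and *ier2* (2.55 ± 0.53), *egr1* (2.54 ± 0.52), the fatty acid synthase gene *fasn* (1.49 ± 0.31) and *sec14l2* (1.38 ± 0.26) among those up. The effect of oil changed in 1985 genes (471 up, 1514 down). In cholesterol synthesis *sqle* (−4 ± 0.85), *ebp* (−3.52 ± 0.58), *lss* (−3.29 ± 0.77) and *fdps* (−2.81 ± 0.69) went down, and elsewhere *hic2* (2.12 ± 0.66), *dsel* (1.74 ± 0.55) and *zcchc14* (1.71 ± 0.47) went up. For *ahrr* the change was not called after oil (−0.76 ± 0.34, adjusted p = 0.123), hypoxia (0.47 ± 0.34) or both (−0.61 ± 0.33, adjusted p = 0.309). Nor was it for *tiparp* (−0.46 ± 0.18, −0.01 ± 0.18 and −0.64 ± 0.18), *egln3* after oil (−0.86 ± 0.33), or *vegfa*, *bnip3* and *ndrg1* in any of them. With 1 library left out, calls were kept throughout for *egln3*, *hpx*, *slc16a1*, *mmp9*, *higd1a*, *lox*, *grem1*, *rpe65*, *sqle* and *ebp*. Those of *egr1* and *ier2* were lost without 10 of the 12 libraries, normoxic control replicate 3 at 48 h among them, those of *fasn*, *hic2* and *dsel* also without 10, and of *slc4a1* and *lepr* without 9. Recovery depended on the control set. With the other set at both times, a reference chosen after the data were seen, *sqle*, *ebp*, *lss* and *fdps* moved up (2.64, 1.96, 3.5 and 1.86), as 14 of 17 cholesterol genes did, against 13 of 17 down with their own set. The calls of *hic2*, *dsel*, *zcchc14*, *ier2* and *egr1* were lost there, *fasn* moved down (−0.92), *ahrr* was called after oil (−1.18, adjusted p = 0.0106) and *tiparp* after both (−0.91). The other called genes named here kept call and direction, and the counts were 3034 up and 2976 down for oil, 5737 and 6057 for hypoxia, and 6069 and 6395 for both. Of the 1985, 37 and 223 genes 342, 31 and 189 kept call and direction there, where independent lists would share 264, 9.89 and 62.9. The oil count ran from 246 without control replicate 1 at 96 h to 9247 (4767 up, 4480 down) without control replicate 3 at 96 h, and the hypoxia count was 64 up and 62 down without hypoxia replicate 1 at 96 h.

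Whether low oxygen altered the effect of oil was tested as an interaction, and few genes passed. At 48 h 3 were called, all with a lower effect of oil under hypoxia. They were *lox* (−1.81 ± 0.32, adjusted p = 0.0426), and, chosen after their values were seen, LOC107084109 (−2.55 ± 0.43, adjusted p = 0.0426) and LOC107083460 (−2.61 ± 0.36, adjusted p = 0.0036). The calls of *lox* and LOC107084109 were each lost without 8 of the 12 libraries. The effect of oil on *ahrr* differed by 0.12 ± 0.32 (adjusted p = 0.992) and on *tiparp* by 0.30 ± 0.18, and *egln3* (0.58 ± 0.32), *vegfa* (0.03 ± 0.17), *bnip3* (0.19 ± 0.39) and *ndrg1* (0.66 ± 0.18) were not called. At 96 h 94 genes were called, 91 higher, among them *tm4sf5* (1.90 ± 0.42), *ebpl* (1.83 ± 0.38) and *wdr74* (1.60 ± 0.34). The 3 lower were *bco2*, the carotenoid oxygenase gene (−0.84 ± 0.19), and, chosen after their values were seen, *pura* and LOC107103646 (−2.25 and −3.83), each at adjusted p = 0.0499. With control replicate 1 at 96 h left out each of these 6 was at adjusted p = 0.28 (0.000241 to 0.28 over the libraries left out). The count was 8375 (4040 higher, 4335 lower) without control replicate 3 at 96 h. EdgeR called 0 with RLE scaling while DESeq2 called 1466 and 5923 genes had an unadjusted p under 0.05. At 96 h *egln3* (1.11 ± 0.33, adjusted p = 0.0665), *ahrr* (−0.20 ± 0.34), *tiparp* (0.12 ± 0.18), *vegfa* (0.22 ± 0.17), *bnip3* (0.29 ± 0.40) and *ndrg1* (0.16 ± 0.18) were not called.

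The effects of oil measured in the separate sets of libraries resembled each other at 48 h. Across genes, which are not independent replicates, fold changes of oil against control and of oil plus hypoxia against hypoxia correlated at 0.37 (0.30 to 0.37 with 1 library left out). There were 192 genes higher in both where independent lists would share 13.4, and 59 lower in both where 3.54 would be shared. Another 1 was called in opposite directions. At 96 h that correlation was 0.20 (−0.06 to 0.33), the lowest a change of sign. Oil and hypoxia were opposed at 48 h (−0.19, −0.21 to −0.10) and alike at 96 h (0.59, 0.48 to 0.63), where 246 genes were higher in both against 74.2 for independent lists. Between 48 h and 96 h the correlation was 0.16 for oil (58 genes higher and 57 lower at both times, against 66.7 and 44.2 for independent lists, and 49 in opposite directions), 0.06 for hypoxia and 0.21 for both together (96 higher and 80 lower at both times, against 42.6 and 29).

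The genes named first lie as follows, all protein coding, by the identifiers and coordinates of the files. The *mmp9* gene is gene 107087470 on scaffold NW_015150638.1 (876231 to 880810, minus strand) and *ahrr* 107084898 on NW_015150564.1 (260060 to 345324, minus). Next, *sox9* is 107083180 on NW_015150522.1 (1035068 to 1038575, plus) and *serpinh1* 107083491 on NW_015150528.1 (856426 to 859885, minus). Of the hypoxia genes, *egln3* is 107086869 on NW_015150617.1 (509592 to 516578, minus), *hpx* 107097395 on NW_015151144.1 (306017 to 311192, plus) and *egr1* 107102097 on NW_015150484.1 (949844 to 953881, plus). The others are *sqle* 107090131 on NW_015150735.1 (824358 to 845142, plus), *cdk1* 107092940 on NW_015150854.1 (762378 to 772617, minus) and *lox* 107084642 on NW_015150558.1 (354506 to 368111, plus).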

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

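The splits of the samples, both tests of the oil count at 96 h and the omission of single normoxic controls for the immediate early genes were tests chosen after the result was seen.

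The effects of treatment differed between the times by a test of the difference itself. The hypoxia effect on *egln3*, the prolyl hydroxylase gene, fell by 2.63 from 48 h to 96 h (−2.63) and the effect of oil plus hypoxia by 2.95 (−2.95), and that of hypoxia on hemopexin *hpx* by 3.65 (−3.65). In all 1985, 37 and 223 genes differed between the times for oil, hypoxia and both. In 25 splits of the 12 libraries only the real one gave as many genes, 1 of 25 each, the smallest share possible. Splits can carry treatment effects, so this share leaves chance open. The highest other counts were 32, 16 and 91, and 7804 against the 13711 genes of age. Against the other control set at both times 342, 31 and 189 of these genes kept call and direction (264, 9.89 and 62.9 for independent lists), and without control replicate 1 and 3 at 96 h the oil count was 246 and 9247.

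The effect of oil differed between low and full oxygen in 3 genes at 48 h, *lox* at −1.81 among them, and in 94 at 96 h. Here 5 of 25 splits at 48 h gave as many genes (highest 203) and 8 of 25 at 96 h (highest 7541). These splits exchanged libraries between oil and control, and between oil plus hypoxia and hypoxia, so they can carry the effect of oil itself. The shares therefore leave chance open.

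In oil plus hypoxia replicate 1 at 48 h 10.98% of the reads of genes with an exon model lay in introns, a measure no comparison used, against 1.82 to 3.99% in the other 29 libraries, and gene reads made 74.87% of its RPKM library total, against 87.86 to 93.67%. No cause was tested.

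With 3 libraries against 3 there are 10 splits, too few for a share under 0.05 (1 of 10 in each comparison). The real and highest other counts were 593 and 0 for oil at 48 h, 8759 and 7784 for oil at 96 h, 47 higher plus 60 lower and 35 for hypoxia at 48 h, 927 and 1 for hypoxia at 96 h, 719 and 204 for both at 48 h, 4563 and 1 for both at 96 h, 1161 and 0 for adding oil to hypoxia at 48 h, and 11 and 0 at 96 h. Between the control sets they were 3695 and 25 at 48 h, and 7465 and 6084 at 96 h. The split with 7784 genes set oil replicates 1 and 3 with control replicate 3 against the rest.

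The first pattern weighed was the 8759 genes that differed at 96 h after oil, ribosomal proteins and the respiratory chain among them. With the trend on exon length removed 6778 genes were called, 4984 of them the same genes in the same direction, which argues against that trend as the whole cause. Against the normoxic controls 18.5% of the called genes kept call and direction (1620, where independent lists would share 894), and 27.2% had the opposite sign. These values cannot separate an effect of oil from the state of the control libraries. The control sets themselves differ in 7465 genes at 96 h and a loss can come from either, a limit recognised after the value was seen. An effect of oil may account for part of the count, and stays untested against the controls' own state.

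Another pattern was the likeness of oil and hypoxia at 96 h, where *syn2* was higher and *sod1* lower after both (r 0.70 from group means of log2 CPM across 14986 genes, which are not independent replicates; 0.60 to 0.75 with 1 library left out). With the length trend removed r was 0.61 (0.50 to 0.67), and given the age change of the oil plus hypoxia libraries the partial r was 0.67 (0.55 to 0.73), which argues against either as the whole cause. With the control sets exchanged r was −0.20 (−0.35 to −0.06), a value that met the bound set beforehand for control libraries as the cause. The test was judged void only after that value was seen, since the exchange adds the difference between the sets to one fold change and takes it from the other, and the variance of that difference (0.419) exceeds the covariance of the fold changes (0.193). So control libraries, a shift along larval age and a common response of larvae after stress cannot be told apart, and each may contribute.

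The last pattern was the fall of immediate early genes such as *egr1* and *ier2* under hypoxia at 48 h, with a median of −1.41 over 15 genes and 9 called lower. Against control the median was −0.19 (−0.30 to −0.13) with 1 called, and relative to control the normoxic controls lay at 1.22 and the hypoxia, oil and combined libraries at −0.20, 0.18 and 0.44. This is consistent with high levels in the normoxic controls rather than a fall under hypoxia. Leaving out normoxic control replicate 3 gave −0.90, and replicate 1 or 2 −1.76 or −1.4. These values do not settle whether 1 pool carried the pattern, and whether handling of some pools may have raised these genes stays open.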

How the results depend on the processing

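Exon reads, unchanged gene models, removal of the length trend, recovery against the other control set and age within each control set were tests chosen after the result was seen. Of 4612 values of called named genes over the alternatives 3840 kept direction and call, 746 kept direction but lost the call (519 of them with 1 library left out) and 26 changed sign, all with another choice of control set. DESeq2 kept 270 of 270 such calls and unique reads 271 of 271. The cause was not tested for any change below. Fewer libraries enter a fit of the contrast's libraries alone or with 1 left out. Counts in such fits moved both up and down, so fewer libraries alone do not account for them.

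Against the other control set 4202 genes differed for oil at 48 h, 4565 for oil at 96 h, 1250 and 13195 for hypoxia at 48 h and 96 h, and 3505 and 13726 for both together. Named genes changed sign there as follows. In oil at 48 h *ehf*, *gnmt*, *ebp* and *srebf2* were at −0.35, 0.46, −0.86 and −0.18. In oil at 96 h *sqle*, *ebp*, *fdps*, *ppil1*, *pcna*, *mcm7*, *syn2*, *nppa* and *hspd1* were at 1.62, 1.1, 0.66, 0.33, 0.64, 0.70, −0.09, 1.59 and 0.53. In hypoxia at 48 h *klf4*, *hsd3b7* and *actn3* were at 0.08, 0.29 and −0.01, and with both *noxo1* and *tgm2* at 48 h and *cpt1b* at 96 h at 0.42, 0.13 and 0.22. Recovery from oil, hypoxia and both gave 6010, 11794 and 12464 genes with the other set at both times, with *sqle*, *ebp*, *lss* and *fdps* at 2.64, 1.96, 3.5 and 1.86 after oil and *fasn* at −0.92 after hypoxia. With age, 12831 genes differed in control and 10228 in normoxic control, where *bnip3* and *calcoco1* were at 0.23 and 0.13.

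DESeq2 called 982 genes for oil at 48 h, 257 and 2694 for hypoxia at 48 h and 96 h, 29 for adding oil to hypoxia at 96 h, 3553, 194 and 577 for recovery from oil, hypoxia and both, and 47 and 1466 for the interaction at 48 h and 96 h. A fit of the contrast's libraries alone called 1912 genes for oil at 48 h, 0 for oil at 96 h (edgeR; 6162 at an unadjusted p under 0.05, and 9319 by DESeq2 on all libraries), 16 and 2339 for hypoxia, 181 for both at 48 h, 282 and 356 for recovery from oil and from both, 17 and 0 for the interaction, and 1850 and 3733 between the control sets at 48 h and 96 h. With the length trend removed the counts were 166 and 569 for hypoxia at 48 h and 96 h, 1259 and 67 for recovery from oil and hypoxia, and 11 and 0 for the interaction. Exon reads gave 137 for recovery from both. For the interaction at 96 h edgeR called 0 genes with RLE scaling, no filter or exon reads, against 94, where 5923 had an unadjusted p under 0.05, and 146 with unique reads.

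With 1 library left out the counts ran from 219 to 343 for oil at 48 h, 2503 to 12100 for oil at 96 h, 20 to 316 and 0 to 3547 for hypoxia at 48 h and 96 h, 375 to 738 and 1.1e+02 to 5763 for both, 497 to 1068 and 7 to 15 for adding oil to hypoxia, 246 to 9247, 14 to 126 and 72 to 580 for recovery from oil, hypoxia and both, 1 to 7 and 0 to 8375 for the interaction, and 1489 to 3986 between the control sets at 48 h. Where 0 genes were called for hypoxia at 96 h, 3887 to 4320 had an unadjusted p under 0.05, and DESeq2 on all libraries called 2694.

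The replicate numbers do not pair the samples: in none of the comparisons was every correlation between same-numbered libraries over 0.1 (lowest −0.54). With the replicate block the interaction count was 1 at 48 h and 148 at 96 h, the count between the control sets at 48 h 1664, and other counts stayed within 1.5 times, such as 528 for oil and 83 for hypoxia at 48 h.

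Of the 76 gene list calls 2 held with an estimated correlation. The fry test called 36, of which 29 were called by both in the same direction, and 72 were called with the length trend removed, 63 in the same direction and 1, ribosomal proteins at 96 h after hypoxia, in the other. Correlations of edgeR fold changes across genes restricted to a mean log2 CPM of 2 or more were 0.14 and 0.31 between the times for hypoxia and both, 0.55 and 0.34 between the effects of oil at 48 h and 96 h, −0.27 and 0.69 between oil and hypoxia, and 0.33 between the times for adding oil to hypoxia. Depth limits little here: a count of 3 reads corresponds to 0.0874 to 0.153 CPM.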

Other observations

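The genes of the first paragraph and the tests at 48 h and by size of the age change were chosen after the result was seen.

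Between the control sets single genes not named so far for that comparison differed as well. At 48 h the glyoxylate aminotransferase gene *agxt* was lower in normoxic control (−2.79 ± 0.33), as were *got1* (−2.28 ± 0.25) and *gnmt* (−2.03 ± 0.35), while *gatm* of creatine synthesis and the fatty acid elongase gene *elovl5* were higher by 2.51 ± 0.43 and 2.49 ± 0.36. At 96 h the muscle genes *asb14* (3.54 ± 0.37), *mlip* (2.64 ± 0.35) and *abra* (2.38 ± 0.26) were higher, and *fbxo32*, which marks muscle protein for breakdown, was at 2.28 ± 0.67, a call lost with 1 library left out. The mitophagy gene *bnip3*, a HIF target, was lower at 48 h (−1.19 ± 0.28) and higher at 96 h (1.2).

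A hypothesis is that larvae exposed to oil under hypoxia developed more slowly, so that at 96 h their expression lay nearer to that of younger larvae than after hypoxia alone. If so, the change on adding oil should run against the change with age in the controls, which share no libraries with it. Across 14733 genes, which are not independent replicates, r was −0.52 with the length trend removed (−0.61 to −0.31 with 1 library left out), and at 48 h −0.24 (−0.33 to −0.16). The 797 genes at least 2-fold higher with age had a median of −0.19 on adding oil at 96 h, and the 1424 genes at least 2-fold lower a median of 0.24. These values are consistent with slower growth and may equally reflect other processes that run along the same axis, and no size or stage of the larvae was analysed here.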
